A study of Mus musculus with 6 samples.

How the data were processed

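Total RNA of embryoid bodies was labelled with Cy3 and hybridised to 1-colour Agilent mouse arrays, per the labels' protocols. There were 6 arrays: 2 of WT, 2 of line TKO_26 and 2 of line TKO_29. Groups and replicate numbers were taken from the sample labels.

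Per the file headers, the scanner files were made with Agilent Feature Extraction 10.5.1.1 and give each spot's intensity as a processed signal, background-subtracted and detrended within the array and not normalised between arrays, with the median pixel intensity of the spot and of its local background and flags for outliers, saturation and signal well above background. The authors also deposited a matrix of log2 values, whose processing is not given in the sources used here. Set against the scanner values, each matrix column followed the log2 median signal of its own array (Pearson r 0.995 to 1.00). The highest r with another array was 0.982 to 0.996. For TKO_29 replicate 1 the values were 0.9962 and 0.996, which hardly tells its column apart. The sorted columns were nearly identical (medians 6.86 to 6.89), as after quantile normalisation without background subtraction. The scale and direction of the matrix were settled in this way, and values are not centred per gene.

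Each array held 59305 non-control spots of 55681 probes. Control spots were left out, spots flagged as outliers were removed (263 probes were lost because an array had no other spot), saturated spots were kept, and repeated spots of a probe were averaged. Probes were named by matching their unversioned accession to a RefSeq gene table of assembly GRCm38.p6. Of 26585 probes with a curated mRNA accession 26166 matched, and 27509 of all probes (49.4%) had a symbol. The arrays were designed on another assembly, so no coordinates are printed, and the table was used only for names, chromosome membership and gene order. From 38.4% to 55.8% of spots per array were well above background (mean 48.5%), so log2 processed signals were scaled by subtracting each array's 75th percentile over the 19178 probes well above background on all arrays. The 75th percentile of the unscaled processed signal ranged from 507 to 2208. A probe entered the tests if it was well above background on both arrays of at least 1 line. The probe with the highest mean signal stood for its gene; 4941 genes had several such probes, and for 17 of these probes disagreed in sign with at least 2-fold both ways.

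Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on line averages, WT n = 1 and TKO n = 2, with 1 residual degree of freedom, WT being assumed to vary like the TKO lines. Each TKO line was compared with WT, and the TKO lines with each other, in 1 fit of the 6 arrays in 3 groups with 3 residual degrees of freedom; these p-values compare the lines, not genotypes. Calls needed a Benjamini-Hochberg adjusted p under 0.05 and a 2-fold difference. Gene lists fixed before the data were examined were tested with camera on line averages (preset correlation 0.01, two-sided, adjusted over 23 lists). The alternatives, camera with an estimated correlation and fry, were run on the 6 arrays in 3 groups. They thus differ from the main test in more than the correlation, and count the arrays of a line as replicates. The lists were pluripotency, Nodal signalling, epiblast and primitive streak, neuroectoderm, neural crest, cardiac muscle, blood, endothelium, visceral and definitive endoderm, parietal endoderm, trophoblast, germline, 2-cell stage, imprinted genes, DNA methylation machinery, proliferation, Hox genes, mesenchyme and fibroblast, epithelium, Wnt targets, hypoxia and glycolysis, stress and p53, and a sex-linked check. Figures and parsing used Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6.

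Genes were named by a rule fixed at the same time: the Tet genes; the 12 largest and 12 smallest differences among genes called on line averages and in both lines; up to 4 members of each list called in both lines, or the member with the largest difference where none was; and 6 genes each way among those called between the TKO lines, of which there were none. Clone, predicted and accession-only names were counted but not named. Where the dimmer group had no array well above background, or only some, the fold is a bound ("at least"): the bright group's mean against the mean of, per array, the higher of the probe's own signal and the lowest signal well above background on that array. Bounds for genes with some arrays above background were added after the results were seen.

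The tests were tested on simulated arrays of 21421 genes with known changes, 10 draws each. With 200 changed genes and lines that vary, requiring both lines recovered 22.2% of genes changed by a log2 of 1, 80.0% at 2, 93.4% at 4 and 98.6% at 6, and called 302.5 unchanged genes on average. The test on line averages recovered 0% at every size with 200 changed genes and lines that vary, and at most 8.2% with lines that do not, so a set of 3000 changed genes was added after that result was seen. There it recovered 1.09%, 39.3%, 81.0% and 91.0% and called 43.7 unchanged genes. It therefore has power only where very many genes change. Without variation between lines, requiring both lines called 0.8 unchanged genes on average.

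Alternatives fixed beforehand were quantile normalisation, normexp background correction (offset 50), the authors' matrix, no filter or a filter on all 6 arrays, the mean of a gene's probes, a variance trend, no fold minimum, an adjusted p under 0.1, leaving out each array, other designs for the technical arrays, and a replicate block. Normexp was planned on mean pixel signals; the median pixel signals were used because the deposited scanner files hold no mean pixel signal. Added after seeing the data were the percentile over all probes, fits without chromosomes 8, X and Y, without saturated genes and with named genes only, list counts under every setting, and a simulation of unchanged lines that deviate from each other.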

Results

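The series asked how mouse embryonic stem cells that lack the TET dioxygenases, the enzymes that oxidise 5-methylcytosine in DNA, differentiate in culture. Stem cells with all 3 Tet genes knocked out (TKO) and wild-type (WT) cells were grown as embryoid bodies, cell aggregates in which stem cells form derivatives of the germ layers. The aggregates formed in hanging drops over 2 days and stayed in suspension for another 8 days, without the self-renewal factor LIF. RNA of 1 WT line and of 2 TKO lines, TKO_26 and TKO_29, was hybridised to 1-colour arrays, 2 arrays per line. The series describes the arrays of a line as technical replicas and does not state whether they share RNA or come from separate cultures. They were treated as technical, so WT had n = 1 line and TKO had n = 2 lines, and p-values over single arrays cover at most the spread within a line. All 6 arrays lay on 1 slide, with the WT arrays in one of its columns and the TKO arrays in the other, so that position on the slide and genotype cannot be told apart.

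Between 38.4% (TKO_26 replicate 1) and 55.8% (TKO_29 replicate 1) of the spots were well above background. TKO_26 replicate 1 was also the noisiest array, with a median coefficient of variation of repeated probes of 14.2%, against 4.32% to 5.61% on the others. Over 13260 genes measured without saturation on all arrays, the standard deviation of the difference between the arrays of a line was 0.30 for WT, 0.38 for TKO_26 and 0.23 for TKO_29 on the log2 scale. It was 0.50 between the means of the TKO lines, 0.74 between WT and TKO_26 and 0.88 between WT and TKO_29. The number of arrays and lines limits the precision of every value. Below, a gene "rose" or "fell" where it was at least 2-fold different from WT in the same direction in both TKO lines, each with a limma adjusted p under 0.05 over arrays. Counts of such genes include some that were above background in only one genotype, whose bound can lie under 2-fold.

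The targeted genes came first. Tet1 fell on its brighter probe, by 1.02 in TKO_26 and by 1.69 in TKO_29 on the log2 scale, while its dimmer probe differed by 0.08 on average. Tet2 fell on the brighter of its probes, by 1.09 in TKO_26 and by 1.90 in TKO_29, with a mean difference of -1.38 on the other. The probes of Tet3 disagreed: the brightest stood 1.05 higher in TKO_26 and fell by 0.62 in TKO_29 without passing the test. The others lay lower in both TKO lines, but neither gives a measured fold. One (-2.60 in TKO_26 and -4.415 in TKO_29) was well above background on both WT arrays and no TKO array. The other (-1.26 in TKO_26 and -1.60 in TKO_29) was so on 1 WT array and both arrays of TKO_29 only. The normalised signals of the brighter Tet1 probe were -0.93 and -1.21 on the WT arrays, -2.01 and -2.17 on those of TKO_26, and -2.69 and -2.81 on those of TKO_29. Where the probes lie relative to the deleted parts is not given in the sources used here, and a probe outside a deleted part checks nothing. The Tet1 call was lost without WT replicate 1, TKO_26 replicate 2 or TKO_29 replicate 2, with differences of -1.21, -1.31 and -1.32, and the Tet2 call without WT replicate 2 or TKO_26 replicate 1, with -1.37 and -1.48.

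The comparison of TKO with WT embryoid bodies asked which genes and cell types depended on the TET enzymes. Genes of blood, vessels, heart and placenta made up the 12 largest log2 decreases among named genes called on line averages and in both lines. The embryonic globins Hbb-bh1, Hbb-y and Hba-x, made by primitive red cells, were well above background on both WT arrays and on none of the 4 TKO arrays, at least 2097-fold, 505-fold and 323-fold lower. Myl7, an atrial myosin light chain, and Icam2, an adhesion molecule of endothelium, fell at least 210-fold and 354-fold, being well above background on 3 and 2 of the TKO arrays. In the other direction Cdh1, which encodes E-cadherin, rose 54.9-fold (log2 difference 5.78 ± 0.38, SE) and was measured on all arrays. The array holds 1 Cdh1 probe. The other 19 epithelial genes, each on its brightest probe, had a median difference of 0.28 and a highest of 1.105. The other probe of Cldn4 lay above that, at 1.30 in TKO_26 and 1.71 in TKO_29, while that of Grhl2 lay at -0.57 and -0.49. A sequence difference under the Cdh1 probe, or a low level particular to the WT line, cannot be told apart from an effect of the genotype.

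Of 21421 genes and unnamed features tested, 2279 passed in both lines, 867 higher and 1412 lower, of which 592 and 1176 had a gene symbol. The stricter test on line averages, which counts a line as 1 replicate, called 194, 33 higher and 161 lower, with adjusted p between 0.0461 and 0.05, and 192 of these also passed in both lines. At an unadjusted p under 0.05, 3849 genes passed it. Higher calls made up 17% of the 194, 37.5% with the authors' matrix values and 32.6% with a variance trend, but 7.4% without chromosomes 8, X and Y, where 6 higher calls remained, and 6.8% without TKO_26 replicate 1. Leaving out those chromosomes also refits the test, and lower calls fell too, from 161 to 75. With adjusted p this close to 0.05, calls on other chromosomes can be lost as well, so these numbers do not count calls by chromosome. Of the 2279, higher calls made up 38%, but 25.6% with normexp. The 194 became 0 without WT replicate 1, without WT replicate 2, without TKO_26 replicate 2 and without TKO_29 replicate 2, 118 without TKO_26 replicate 1 and 597 without TKO_29 replicate 1, and the 2279 became 1423 without TKO_29 replicate 2. In simulated data in which the WT line deviated as the TKO lines do from each other, the requirement of both lines still called 302.5 unchanged genes on average among 21421.

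Among the others of the 12 named genes with the largest log2 decreases were placental and endothelial genes. On bounds the order differs. Ctsj, a placental cathepsin measured on all arrays, fell 101-fold, above the bounds of Stab1, Gimap6 and Ctsq. So did Ctsr and the globin Hba-a1, at least 112-fold and 109-fold, and Tnnt2 (95.0-fold) lay above the bounds of Stab1 and Ctsq. Stab1, a scavenger receptor of sinusoidal endothelium, and Gimap6, a GTPase of immune and endothelial cells, were not well above background on any TKO array and lay at least 85.7-fold and 97.3-fold lower. Cd93, an endothelial surface glycoprotein, fell at least 166-fold and was measured on 3 of 4 TKO arrays. The placental hormones Prl3b1 (at least 177-fold), Prl7d1 (at least 168-fold) and Prl4a1 (at least 115-fold) fell, measured on 3, 3 and 1 TKO arrays, and Ctsq, a cathepsin of trophoblast, was at least 73.8-fold lower. The adjusted p on line averages was 0.0491 for Hba-x and Ctsq and 0.0461 for the other 10 of these 12 genes.

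The 12 named genes with the largest log2 increases, among genes called on line averages and in both lines, were of mixed kinds. On bounds the order differs: Crisp1, Ccnb1ip1 and Pramel7 lie under the 5.15-fold of Dppa3, which was not called on line averages. Zfp874a, a zinc finger gene, was not well above background on either WT array and lay at least 28.1-fold higher in TKO. On the same terms Serpina3m, a protease inhibitor, was at least 12.7-fold higher, Crisp3 and Crisp1, secretory proteins of the reproductive tract and other glands, at least 12.03-fold and 3.96-fold, and Obox6, an oocyte homeobox gene, at least 5.63-fold. Nuggc was at least 7.29-fold higher, Pramel7, expressed in early embryos, at least 5.07-fold, and Ccnb1ip1, a meiotic recombination factor, at least 4.33-fold. Prim2, a DNA primase subunit, rose 21.4-fold and Nlrp4f, an oocyte gene, rose 12.3-fold. No other probe of Prim2 or Nlrp4f entered the tests. As for Cdh1, a sequence difference under the probe or a low level particular to the WT line cannot be told apart from an effect of the genotype. Fgl1, a secreted liver protein, rose at least 7.58-fold and was measured on 1 WT array. These 12 genes had adjusted p between 0.0461 and 0.0491 on line averages.

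**Figure D1:**
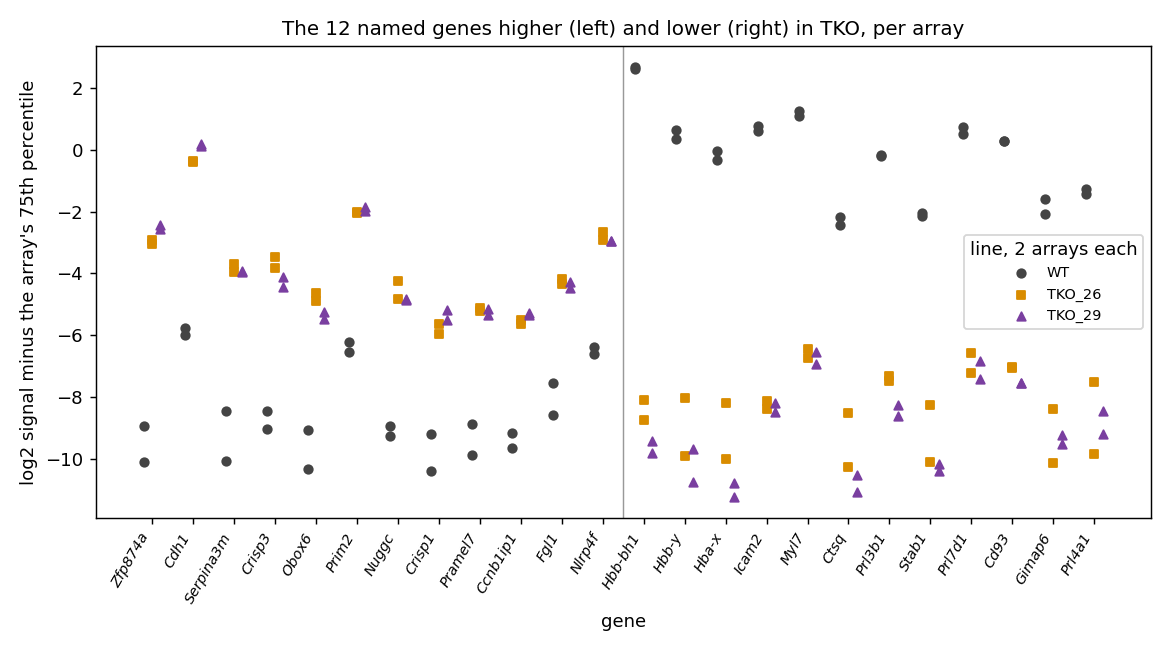
Normalised log2 signal (processed signal minus the array's 75th percentile) of the 12 named genes with the largest increases and the 12 with the largest decreases in TKO. Both sets were picked among genes called on line averages and in both lines. There is 1 point per array (2 arrays each of WT, TKO_26 and TKO_29). The arrays of both TKO lines lie on the same side of the WT arrays for each gene, as for Cdh1 (5.52 higher in TKO_26 and 6.04 in TKO_29); values near the bottom are not well above background.

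Heart, blood and vessel genes fell as groups. Of 24 cardiac muscle genes tested, 21 fell and none rose, among them Hand2 (at least 92.0-fold), a transcription factor of the heart fields, Tnnt2 (95.0-fold), cardiac troponin T, and Myl2 (at least 60.7-fold), a ventricular myosin light chain. Hand2, Myl2 and the blood and vessel genes Hba-a1 and Cdh5 were measured on 3 of 4 TKO arrays, and Sox18 on 2. The list's median log2 difference was -3.60, and -2.95 with dim members at their bounds (camera adjusted p = 4.46e-21; adjusted p = 0.0980 with an estimated correlation). Of 16 blood genes, 13 fell and none rose, including the adult globin Hba-a1 (at least 109-fold) beside the embryonic globins (median -3.20; camera adjusted p = 1.52e-11; adjusted p = 0.0980 with an estimated correlation). Of 18 endothelial genes, 15 fell and none rose (median -3.37; camera adjusted p = 1.27e-11; adjusted p = 0.119 with an estimated correlation). Cdh5, the cadherin of endothelial junctions, fell at least 57.0-fold, the transcription factor Sox18 fell at least 50.1-fold, and Tie1 and Sox7 were at least 73.9-fold and 46.6-fold lower. The probes of Kdr, an endothelial growth factor receptor chosen after its values were seen, disagreed: the brightest had a mean difference of -0.48, while the other lay at -5.87 in TKO_26 and -6.03 in TKO_29. With normexp 7 of 16 blood genes fell. The filter that demands signal on all 6 arrays removes genes lost in TKO. It left 6 blood and 9 endothelial genes, of which 3 and 6 fell. The Sox7 call was lost without either WT array and without either TKO_29 array.

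Endoderm and trophoblast genes also fell. Of 18 genes of a mixed list of visceral (extraembryonic) and definitive (embryonic) endoderm, 11 fell and none rose (median -2.17; camera adjusted p = 5.80e-09; adjusted p = 0.0980 with an estimated correlation). The serum proteins Ttr (40.4-fold) and Afp (at least 29.7-fold), the endocytic receptor Cubn (at least 46.7-fold) and the apolipoprotein Apob (at least 14.5-fold) were among the largest decreases. Cubn was measured on 3 of 4 TKO arrays, as were Prl3d1 and Cdx2 below. The Afp call was lost without WT replicate 1, and the Apob call without either WT array. Of 12 genes of parietal endoderm, 5 fell and none rose (median -1.15; camera adjusted p = 8.82e-05; adjusted p = 0.124 with an estimated correlation). These included Srgn, a proteoglycan core protein (8.98-fold), Lama1, a laminin chain (5.44-fold), Pth1r, the parathyroid hormone receptor (3.29-fold), and Nid1 (2.64-fold), whose other probe, above background on 1 WT array and 2 TKO arrays, differed by -0.06. Of 13 trophoblast genes, 5 fell and none rose (median -1.48; camera adjusted p = 0.0036; adjusted p = 0.230 with an estimated correlation), among them the hormone Prl3d1 (at least 37.0-fold) and the transcription factors Elf5 (at least 10.1-fold) and Cdx2 (at least 7.23-fold). Over genes above background on all 6 arrays the trophoblast median was 0.15 and the list did not pass (adjusted p = 0.893).

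Imprinted, Hox and mesenchymal genes shared the direction. Of 26 imprinted genes, which are expressed from 1 parental allele, 9 fell and 1 rose (median -1.01; camera adjusted p = 2.30e-07; adjusted p = 0.119 with an estimated correlation). Plagl1, a growth-regulating zinc finger gene, fell 41.1-fold on its brightest probe, with mean differences of -5.43 and -0.96 on the others, the latter above background on 1 WT array and 2 TKO arrays. Dlk1, a Notch ligand homologue, fell 8.78-fold and Snrpn, a splicing factor gene, rose 3.15-fold; its call was lost without any 1 of the arrays other than TKO_26 replicate 2. Of 15 Hox genes, 6 fell and none rose (median -1.15; camera adjusted p = 0.00106; adjusted p = 0.119 with an estimated correlation), and these were mostly of the Hoxb cluster, with Hoxb2 and Hoxb4 at least 10.4-fold and 11.7-fold lower and Hoxb5 and Hoxb8 at least 8.88-fold and 4.17-fold lower. Hoxb2 and Hoxb4 were measured on 3 of 4 TKO arrays, and the calls of Hoxb5 and Hoxb8 were lost without either WT array and without either TKO_29 array. The Hox count was 3 without WT replicate 1, without WT replicate 2 or without TKO_29 replicate 1, and 2 without TKO_29 replicate 2 or with normexp. With signal demanded on all 6 arrays only 1 Hox gene was tested and 0 fell, and without the filter 39 were tested and 3 fell. Probes of Hoxb3 disagreed: the one that stood for it differed by 0.25 and did not pass. The other, above background on both WT arrays and no TKO array, lay at -4.35 in TKO_26 and -5.55 in TKO_29. Of 20 mesenchyme and fibroblast genes, which feeder cells would also express, 10 fell and none rose (median -1.13; camera adjusted p = 1.72e-04; adjusted p = 0.1225 with an estimated correlation). Twist2, a mesenchymal transcription factor, fell 16.7-fold, the receptor Pdgfrb fell 9.06-fold, Fbn1, encoding fibrillin, fell 6.92-fold and the collagen Col3a1 fell 5.47-fold.

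Genes of pluripotency, the germline and the 2-cell stage moved in the other direction. Of 24 pluripotency genes, 8 rose and none fell (median 0.69; camera adjusted p = 3.96e-04; adjusted p = 0.119 with an estimated correlation). Dppa3 rose 5.15-fold, Tcl1 rose 3.86-fold and Prdm14, a repressor of differentiation, rose 3.42-fold. Nanog rose 4.06-fold on its brighter probe and differed by -0.15 on the other, and Pou5f1, named after its values were seen, differed by 0.41 without passing. The count was 5 without TKO_29 replicate 2, and Nanog was among the calls lost. Of 19 germline genes, 6 rose and none fell (median 0.78; camera adjusted p = 0.00135; adjusted p = 0.119 with an estimated correlation), including Stra8 (at least 5.12-fold), a gene of meiotic entry, the RNA-binding protein gene Dazl (at least 3.17-fold), Stk31 (at least 3.91-fold, measured on 1 WT array) and the helicase gene Ddx4 (3.54-fold). Of 6 genes of the 2-cell stage, 3 rose, Zscan4c (at least 2.47-fold), Tcstv3 (at least 2.25-fold) and Zscan4f (at least 2.96-fold, measured on 1 WT array), with a median of 1.29, or 1.07 with dim members at their bounds (camera adjusted p = 0.0036; adjusted p = 0.124 with an estimated correlation). With normexp 2 germline genes rose. No gene of the 2-cell stage (0) rose with normexp, with the authors' matrix values or with signal demanded on all 6 arrays, which left 2 of them. Dazl and Tcstv3 were measured on 3 of 4 TKO arrays, and the calls of Dazl, Tcstv3 and Zscan4c were lost without TKO_29 replicate 1, WT replicate 1 and TKO_29 replicate 2, respectively.

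The epithelial list passed with a small median of 0.33 (camera adjusted p = 0.00938; adjusted p = 0.330 with an estimated correlation). Among its 20 genes, each on its brightest probe, only Cdh1 and the junction protein gene Tjp3 (2.15-fold) rose. Without the genes of chromosomes 8, X and Y, which removes Cdh1, the list did not pass (adjusted p = 0.05004), and the Tjp3 call was lost without WT replicate 2 or TKO_29 replicate 2. Of 18 hypoxia and glycolysis genes, 3 rose and none fell, namely Ankrd37 (3.63-fold), a target of hypoxia, and the enzyme genes Aldoc (2.21-fold, saturated on 1 array) and Pdk1 (2.21-fold). Without saturated genes 2 rose. That list had a median of 0.48 (camera adjusted p = 0.0219; adjusted p = 0.168 with an estimated correlation) and did not pass without WT replicate 2 (adjusted p = 0.0648); the calls of Aldoc and Pdk1 were lost, leaving 1, without WT replicate 1 or without either TKO_29 array.

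For the neural lists no direction passed with camera on line averages. With fry over the 6 arrays neuroectoderm passed as higher (fry adjusted p = 0.00654) and neural crest as lower (fry adjusted p = 1.47e-04). Nodal signalling and the epiblast list also passed with fry as higher, and stress and p53 as lower. Of 24 neuroectoderm genes, 4 rose and 2 fell (camera adjusted p = 0.148), with Pax3 3.54-fold and Pax7 at least 1.52-fold higher, and Tubb3, a neuronal tubulin, 3.66-fold lower. Pax7 and Erbb3 were measured on 3 TKO arrays, as was Mesp1. Ncam1 fell 3.01-fold and its other probe, above background on 1 WT array and 3 TKO arrays, differed by 0.26. Of 11 neural crest genes, 2 rose and 4 fell (adjusted p = 0.768), among them Erbb3 (at least 2.42-fold higher), Sox10 (at least 1.72-fold higher, measured on 1 WT array and 3 TKO arrays), Snai2 (7.51-fold lower) and Ednrb (at least 4.80-fold lower, measured on 2 TKO arrays). Genes of the epiblast and primitive streak (14 tested, adjusted p = 0.463) had 1 increase, Gsc (2.72-fold), and 1 decrease, Mesp1 (at least 4.79-fold), a factor of cardiac mesoderm. Nodal signalling (12 tested, adjusted p = 0.401) had 1 of each, Gdf3 (2.13-fold higher, 0.57 on its other probe) and the Nodal antagonist Cer1 (2.66-fold lower). Of 18 genes of the DNA methylation machinery only Apobec1, a cytidine deaminase, rose (2.66-fold; list adjusted p = 0.866). Among 13 Wnt targets only Lgr5 fell (2.69-fold; list adjusted p = 0.866), and the list's median of -0.14 and its test had opposite signs. No gene passed among 18 proliferation genes (adjusted p = 0.300; the largest difference was 1.002 for Mcm3, saturated on 1 array) or 15 stress and p53 genes (adjusted p = 0.228; -0.97 for Cdkn1a). Probes of 9 of the 18 proliferation genes were saturated on at least 1 array, which compresses differences.

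Several of these calls rested on single arrays. The Tubb3 call was lost without any 1 of the arrays other than WT replicate 2, that of Erbb3 without any other than TKO_26 replicate 2, and that of Pax7 without WT replicate 1. The Sox10 call was lost without WT replicate 1, TKO_26 replicate 2 or either TKO_29 array, and that of Lgr5 without either WT array or TKO_26 replicate 1. Gdf3 lost its call without WT replicate 2 or either TKO_29 array and Apobec1 without either TKO_29 array, while Mcm3 passed without TKO_29 replicate 1. Increases among neuroectoderm genes numbered 2 without WT replicate 1 or either TKO_29 array, and 0 neural crest genes rose without those same arrays.

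In all, 15 of 23 lists fixed before the data were examined passed with camera at its preset correlation, 9 lower and 6 higher. With an estimated correlation, tested over the 6 arrays and not on line averages, 0 passed. Adjusted over the list alone, the numbers of genes that passed in both lines matched those above except for cardiac muscle (22 lower), imprinted genes (10 lower), Hox genes (1 higher) and neuroectoderm (5 higher). On line averages 11 cardiac, 7 blood, 5 endothelial, 4 endoderm and 2 trophoblast genes fell, and adjusted over the list alone 22, 13, 14, 12 and 7. The same test raised 0 pluripotency and 0 germline genes, and 5 of each adjusted over the list alone. No list's median changed sign under quantile, normexp, all-probe percentile or matrix values, but several shrank. With normexp they were -1.90 for blood, 0.66 for the 2-cell stage, 0.45 for the germline and 0.30 for hypoxia and glycolysis. With the matrix values they were -2.44 for cardiac muscle, -0.95 for trophoblast and -0.53 for Hox genes.

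**Figure D2:**
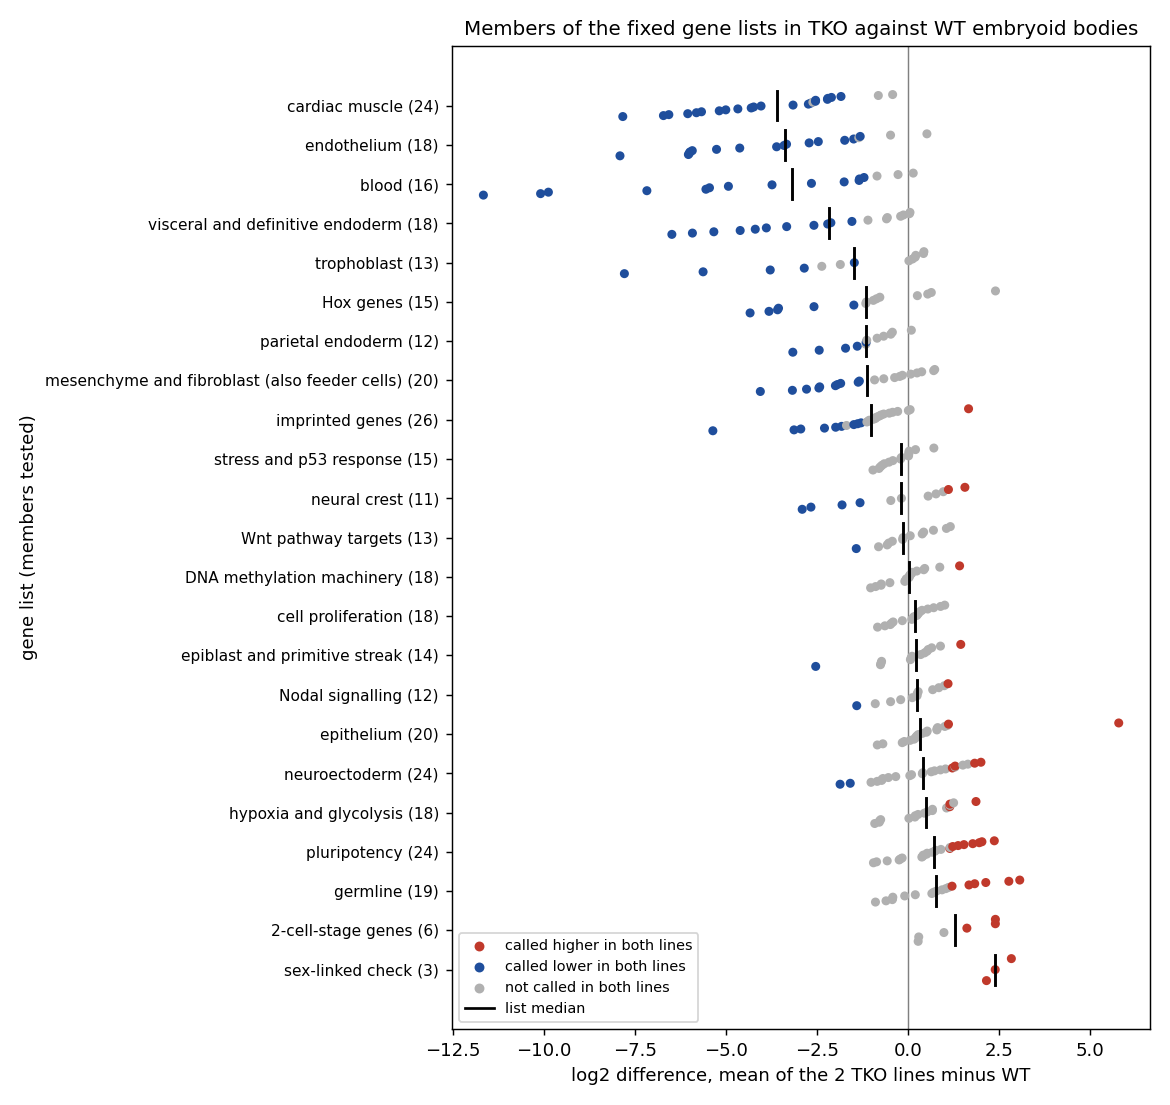
Log2 difference of each tested member of the 23 fixed gene lists (mean of the TKO lines minus WT; 1 point per gene, number tested in parentheses, vertical bar at the list median), coloured by whether the gene passed in both TKO lines. The medians of cardiac muscle, endothelium and blood are -3.60, -3.37 and -3.20, and their order changes with the processing; points for dim genes overstate what is measured.

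Genes of chromosome 8 and the Y chromosome moved with the genotype beside these groups. The median of 783 chromosome 8 genes was 0.45 higher in TKO, 0.50 above the median of the other chromosomes (0.48 in TKO_26 and 0.49 in TKO_29), and 73.2% of them lay higher. Medians of the other autosomes and X ranged from -0.10 to 0.02, and 0 of 10000 random sets matched on signal reached the chromosome 8 value. Cdh1 lies on chromosome 8. Of the sex-linked list, Ddx3y rose 7.12-fold and Eif2s3y rose 4.43-fold (list of 3 genes: camera adjusted p = 6.17e-04; adjusted p = 0.121 with an estimated correlation). Uty also passed, but it was above background on no WT array and on 3 TKO arrays, was at least 1.24-fold higher, and lost its call when any 1 array was left out; its other probe was above background on no array. Xist, the RNA of X inactivation, was not well above background on either WT array on any probe. Kdm5d, also on that list, was well above background on no array.

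**Figure D3:**
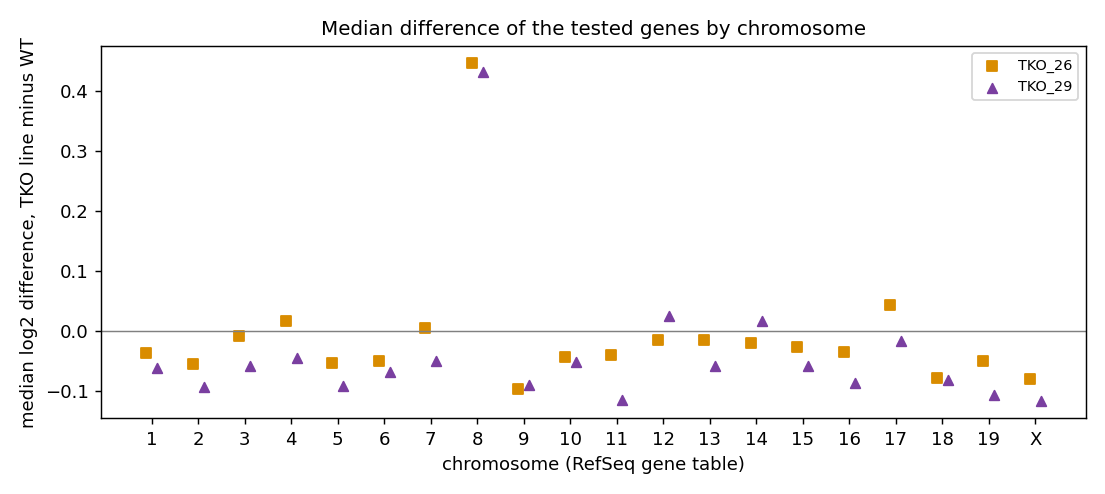
Median log2 difference between each TKO line and WT over the tested genes of each chromosome (squares TKO_26, triangles TKO_29; Y left out because 5 genes were measured). Chromosome 8 stands at 0.45 and 0.43, and the other chromosomes lie between -0.12 and 0.04.

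Both TKO lines were compared with the same WT arrays. TKO_26 differed from WT in 2868 genes (1199 higher, 1669 lower) and TKO_29 in 4148 (1747 higher, 2401 lower); for TKO_29 higher calls made up 42.1%, but 52.2% with quantile normalization and 27.4% with normexp. The count for TKO_26 was 1730 without WT replicate 1, and that for TKO_29 was 2437 without TKO_29 replicate 1 and 2122 without TKO_29 replicate 2. The lines' changes correlated across genes with Pearson r = 0.85, where unchanged lines simulated against shared WT arrays gave 0.50 (highest 0.53 of 100). With array spread alone the simulated covariance was 0.07, against 0.96 observed, and 0 genes were shared. With lines that also deviated from each other as the TKO lines do, WT included, r was again 0.50, the covariance 0.22 (highest 0.24) and the overlap 292.3 genes (highest 353), against 2279 observed. That simulation was added after the results were seen, and how far a WT line deviates was not measured. Independent lists of these sizes would share 97.8 higher and 187 lower genes, against 867 and 1412. Part of the excess may come from the shared WT line. With 1 WT line its own deviation enters both comparisons, and splitting its arrays would not remove it. Without TKO_26 replicate 2, which leaves that line with its noisiest array, r was 0.57.

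Between TKO_26 and TKO_29, limma called 0 genes (smallest adjusted p = 0.0564), although 4787 had an unadjusted p under 0.05 and 1159 of these were at least 2-fold different. Other settings called 246 (authors' matrix values), 337 (above background on all arrays) and 483 (variance trend) genes, and 1512 without TKO_26 replicate 2, so the 0 does not show that the lines were alike. No gene list differed between the lines; the smallest adjusted p, 0.0826, was shared by the pluripotency, Hox and epithelial lists.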

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

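No named gene that was called and no list that passed reversed its direction. Other called genes were not followed singly. Of 1183 values of single named genes under other settings 1057 kept their side of the threshold, 124 were no longer called in both lines and 2 became called; of 413 for single lists these numbers were 386, 22 and 5. The fits with the percentile over all probes, without chromosomes 8, X and Y, without saturated genes and with named genes only were chosen after seeing the data. The 194 calls of TKO against WT on line averages became 0 with quantile normalisation, 0 without the filter and 0 with signal on all 6 arrays, 821 with normexp, 1812 with the authors' matrix, 306 with the mean of probes, 1520 with a variance trend, 81 without chromosomes 8, X and Y, 505 without saturated genes, 942 with named genes only, 937 at an adjusted p under 0.1, and 0 to 597 when 1 array was left out. Treating the arrays as separate samples gave 3109, with the line as a random block 2269, and the mean of both lines in the 3-group fit 3493. TKO_26 against WT (2868) became 1414 with normexp, 1413 without the filter, 1501 with signal on all arrays, 5017 without a fold minimum and 1730 to 3795 with 1 array left out; TKO_29 against WT (4148) became 2668, 2552, 2536, 7678 and 2122 to 4453, and the genes shared by both lines (2279) 1195, 1281, 1186, 4138 and 1423 to 2196. TKO_26 against TKO_29 (0) became 246 with the matrix, 337 with signal on all arrays, 483 with a variance trend, 1 with the percentile over all probes, 271 without saturated genes, 619 at an adjusted p under 0.1, and 0 to 1512 with 1 array left out. The correlation of the lines' changes (0.85) was 0.51 without the filter, which admits noise near background, and 0.57 to 0.88 with 1 array left out. Of 23 lists, 15 passed; 0 did with an estimated correlation, 20 with fry, these 15 among them, 12 to 15 under the others, and 14 to 15 with 1 array left out. A line left with 1 array was assumed to vary like the others. Apart from the filters, the cause of these changes was not tested. Without the filter the median of all genes was -0.24, against -0.04. Few spots above background (38.4% on TKO_26 replicate 1) limit what can be said of dim genes.

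The replicate numbers do not pair the samples: deviations of same-numbered arrays correlated at 0.17 for WT and TKO_26, -0.16 for WT and TKO_29 and -0.23 for the TKO lines. With the number as a replicate block the counts were 2778 (TKO against WT over 6 arrays, against 3109 without it), 2594, 3988 and 0 for the single comparisons, 2079 for both lines and 14 lists. A slide block was not run because all arrays lay on 1 slide.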

Other observations

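The 11 families below, and the tests on Y-linked genes and on Cdh1, were chosen after the results were seen. The placental prolactins fell nearly as a whole family: of 13 members measured, 11 fell in both TKO lines and none rose, with a median log2 difference of -5.63. Prl2b1 (measured on 3 of 4 TKO arrays) fell at least 92.1-fold and Prl2c5 fell 32.2-fold, while Prl7a1 (above background on no TKO array, at least 4.65-fold lower) and Prl7c1 (measured on 1 TKO array) did not pass. Of 4 placental cathepsins 3 fell, Ctsj 101-fold, Ctsr at least 112-fold (measured on 3 TKO arrays) and Ctsq, and Cts6, above background on no TKO array and at least 5.67-fold lower, did not pass. The prolactin median was -3.97 with normexp and -4.25 with the authors' matrix values. Members of such families can share probe sequence, so single values are less certain than the group.

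Among families with some members known from oocytes and early embryos, 6 of 13 Pramel genes passed as higher and none as lower. Of these only Pramel7, Pramel6 and Pramel39 had bounds above 2-fold (at least 5.07-fold, 4.25-fold and 3.22-fold). Of 8 Nlrp genes 3 passed as higher, Nlrp4f 12.3-fold, Nlrp5 at least 3.61-fold (measured on 1 WT array) and Nlrp4c. Nlrp4c was above background on no WT array and 2 TKO arrays and differed by 0.18 on its other probe. The 8 are not all known from oocytes, and Nlrp1a among them was saturated on all 6 arrays. Most members lay near background in WT: the Pramel median of 1.24 was 0.04, and the Nlrp median of 1.54 was 0, with dim members at their bounds. Other families moved in part or both ways. Of 6 Gimap genes 1 fell, with a family median of -2.93, or -2.13 with dim members at their bounds. Gimap8 and Gimap5, above background on no TKO array, were at least 5.95-fold and 3.23-fold lower but did not pass. Nor did Gimap1 (at least 5.37-fold lower, measured on 1 TKO array), Gimap4 (at least 1.91-fold lower) or Gimap9, which differed by 0.32. Of 7 Serpina3 genes 2 passed as higher (Serpina3c at least 1.65-fold) and 1 fell (median -0.25), and 2 of 13 claudins rose and 2 fell. Of 26 myosins and troponins, non-muscle members included, 12 fell, and both Crisp genes and the only Obox gene measured rose. Of 8 Hoxb genes 5 fell, not counting Hoxb3, whose probes disagreed.

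Genes of chromosome 8 stood 0.50 (log2) above the other chromosomes in TKO. The lowest excess under 4 other normalisations was 0.404. The percentile over all probes shifts every gene of an array alike, so it could not change the excess. The others act on whole arrays too and could hardly remove a shift of a single chromosome, so normalisation was barely tested. Among the 668 genes not called the excess was 0.416, but a median over 783 genes could hardly rest on a few. Dim or saturated probes are argued against by 0.474 among 549 bright unsaturated genes. An additional copy of the chromosome in both TKO lines, for which 3 copies over 2 would give 0.585, may account for it as a hypothesis: 9 of 10 bins of genes in chromosome order had an excess above 0.2, as it requires, but the lowest had 0.182, so this stays open. Features that the array files themselves place on chromosome 8 (152) had excesses of 0.23 and 0.24. A loss from the WT culture of part of its copies, or an effect of the genotype, was not tested, and no DNA was measured.

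The measured Y-linked genes stood higher in TKO: Ddx3y and Eif2s3y were above background in both genotypes, while Rbmy, Ssty1 and Uty were so on 3, 2 and 3 TKO arrays and on no WT array. Kdm5d, a Y-linked gene of the fixed list, was above background on no array of either genotype and was not tested. An XX culture of WT cells that expresses Xist is argued against, since 0 WT arrays had an Xist probe well above background. Fewer cells with a Y chromosome among the WT cells stays open, because its test restated what had been seen and its deciding value, a smallest difference of 1.58, belongs to Ssty1, which was above background on no WT array. Ddx3y and Eif2s3y, at 2.83 and 2.15, stayed well above background on both WT arrays. With 1 WT line, a property of that line and an effect of the genotype also remain open.

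Cdh1 stood far from the other epithelial genes. A larger share of epithelial cells in TKO is argued against by the upper quartile of the other 19 epithelial genes on their brightest probes, 0.788. Probes of Cldn4 disagreed: the brightest differed by 0.28, and the other by 1.30 in TKO_26 and 1.71 in TKO_29. An additional copy of chromosome 8 is argued against by Cdh1's smaller difference among the lines, 5.52. A sequence difference under the probe could matter in lines of mixed background and cannot be told apart from a change in expression, because the array holds 1 Cdh1 probe. A low Cdh1 level particular to the WT line was not tested.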
